A study of Homo sapiens with 20 samples.

How the data were processed

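ChIP-seq was done in Raji cells treated with DMSO or 100 nM JQ1 for 24 h, per the labels' protocols, which also state sonicated nuclei and sequencing libraries made with a TruSeq kit. The deposited files analysed here were 12 peak lists, 1 for each of Myc, RNA polymerase II, E2F1, H3K27ac, H3K4me1 and H3K4me3 in DMSO and in JQ1. Each list has 3 columns, the chromosome, the start and the end of a peak, and no value per peak. Tags, p-values, fold enrichment, false discovery rates and library depth were therefore not used here, and depth and its effect on the lists are unknown. Each list belongs to 1 library in the labels. The submitters' processing notes name BWA 0.6.2, SAMtools, MACS 1.4.1 and MACS2 2.0.9 and the builds mm9 and hg19, without the role of each. Which caller, threshold and control library gave which list is not given in the sources used here. The lists are in hg19 coordinates, since they use its contig names and reach position 249202479 on chromosome 1. Whether starts count from 0 or from 1 is not stated, and positions were used and printed as the files give them.

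Samples were grouped by their titles. The 8 samples without a list here, which include RNA polymerase II phosphorylated at serine 2 or serine 5 and input DNA, were not analysed here. Of them, 1 was put in no group because its title and its antibody label name different forms of RNA polymerase II. Peaks were set against each other with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Peaks overlapped when they shared at least 1 base. As a background, peaks were moved by 200 kb up and down and the mean share of the moved peaks was taken. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and not the spread between cultures. The Myc lists hold 11 and 15 peaks on other contigs, and these were kept.

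Chromatin classes were assigned from the histone lists of the same condition in the order H3K4me3, H3K4me1 with H3K27ac, H3K4me1 alone, H3K27ac alone and none. Shared regions were unions of touching peaks with a peak of both lists, and the log2 ratio of covered bases compares lengths, not signal. Long domains were built from H3K27ac DMSO peaks joined within 12.5 kb, and the longest 5% were taken by length. RNA polymerase II domains joined peaks within 1 kb. The rule for named regions was fixed before the data were examined. It took the top 5 of each kind on the autosomes and X, where the kinds are peaks in DMSO only, peaks in JQ1 only, and shared regions with the highest and the lowest ratio of JQ1 to DMSO. Because the lists hold no tags or p-values, the rule ranked single-condition peaks by width and shared regions by the log2 ratio of covered bases, among regions with at least 5 kb covered in both lists together. These rankings, the distance classes, the Jaccard index and the RNA polymerase II domains were chosen after the columns of the files were known.

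The planned log2 tag ratios, the thresholds on p and on a false discovery rate, the promoter shares, the gene lists and the genes named in advance were left out. The tag ratios and the thresholds needed values that the lists do not carry, and the promoter shares, gene lists and named genes needed an hg19 gene annotation. The gene table at hand is on another build, coordinates were not converted, and no gene list was evaluated. No test between conditions was made, no replicate could be left out, and no p-value is given. The alternatives tried were a reciprocal overlap of 50%, lists cut to equal length by width, broad peaks of at least 1 kb, exchanged histone lists for the classes, other joining distances and shares for the H3K27ac domains, and autosomes and X only. Added after seeing the data were windows of the central 200 bases, peaks merged within 500 bases, domains from the JQ1 list, factor lists cut to 1 length in both conditions, other joining distances for RNA polymerase II and the exchanged H3K4me3 list for its covered bases. The interval functions were tested on simulated lists with known answers and against bedtools 2.31.1, and all 16 of 16 checks passed.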

Results

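Raji cells, a B cell line from Burkitt's lymphoma, were treated for 24 h with 100 nM JQ1, a small-molecule inhibitor of BET bromodomains, or with the vehicle DMSO. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 3 DNA-bound proteins and 3 histone modifications. The proteins were the transcription factors Myc and E2F1 and total RNA polymerase II. H3K4me3 typically marks promoters, H3K4me1 marks enhancers and the flanks of promoters, and H3K27ac marks active promoters and enhancers. The comparison asks where each of these was found on chromatin with and without the inhibitor. The series has 20 samples, of which 12 had a peak list analysed here, 1 for each of the 6 antibodies in each condition. With 1 library per antibody and condition there was no replicate, so no difference between conditions was tested. Exact Clopper-Pearson 95% intervals are given for shares of peaks, and they cover counting error only. The lists hold positions alone, so the depth of each library is unknown and no difference in signal height could be measured. All positions are on the human build hg19, as the files give them, and regions are named by coordinate because no hg19 gene annotation was used here.

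More sites were listed for Myc after JQ1, whereas RNA polymerase II covered fewer bases. The Myc list held 15247 peaks in DMSO and 21562 in JQ1, 1.41 times as many, over 24.9 and 36.0 Mb, at nearly the same median width of 1446 and 1430 bases. RNA polymerase II had 46561 peaks in DMSO and 42469 in JQ1, 0.912 times as many, and covered 45.9 and 32.0 Mb, with the median width at 536 and 430 bases. E2F1 had 4820 and 8122 peaks, covering 2.70 and 17.8 Mb. The H3K4me3 lists were close in size, with 13941 and 13088 peaks over 52.4 and 52.3 Mb. For H3K4me1 14340 and 10095 peaks were listed, over 109 and 90.2 Mb, and for H3K27ac 6663 and 11859 peaks, over 45.3 and 79.8 Mb. The E2F1 lists differed in kind, with a median width of 507.5 bases in DMSO and 2024 bases in JQ1, and a narrowest peak of 59 and 474 bases. The list labelled H3K27ac DMSO was less like its JQ1 partner than like RNA polymerase II by the Jaccard index (0.249 and 0.341), so values that use it are given as those of the list with that label.

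**Figure D1:**
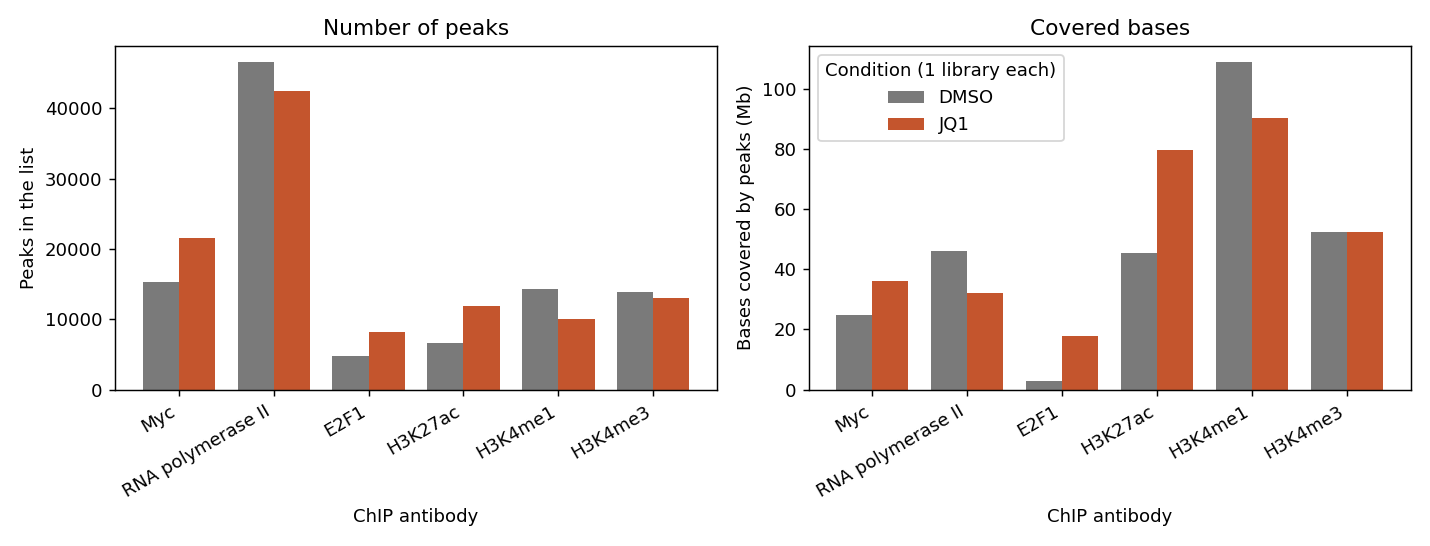
Number of peaks (left axis, peaks per list) and bases covered by them (right axis, Mb) for each ChIP antibody, with 1 grey bar for the DMSO library and 1 orange bar for the JQ1 library. Myc had 15247 peaks in DMSO and 21562 in JQ1, RNA polymerase II covered 45.9 and 32.0 Mb, and H3K4me3 52.4 and 52.3 Mb.

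Nearly all Myc sites seen in DMSO were found again after JQ1, and the JQ1 list held further sites. Of the DMSO peaks, 97.5% (95% interval 97.2 to 97.7) overlapped a JQ1 peak by at least 1 base, against 5.73% when the DMSO peaks were moved by 200 kb. In the other direction, 67.8% (67.2 to 68.4) of the JQ1 peaks overlapped a DMSO peak, against 4.06% when moved. This left 385 peaks in the DMSO list only and 6941 in the JQ1 list only. The JQ1-only peaks were narrower, with a median width of 1068 bases against 1720 for the JQ1 peaks in both. They made up 81.0% of the JQ1 peaks of 500 to 1000 bases and 4.01% of those of 2 kb or more. Whether a more sensitive JQ1 library gave these further peaks was not tested, since depth is unknown. In the 14477 regions with a peak in both lists, the median log2 ratio of covered bases, JQ1 over DMSO, was 0.14, and 80.5% of these regions were wider in JQ1. The regions with the highest ratio of JQ1 to DMSO lay on chromosome 8 at 93026355 to 93032714, where Myc covered 1.24 kb in DMSO and 6.36 kb in JQ1, on chromosome 14 at 65671348 to 65675337, with 1.14 and 3.99 kb, and on chromosome 1 at 117098710 to 117102809, with 1.23 and 4.10 kb. The 5 regions with the highest ratio all overlapped RNA polymerase II, H3K27ac, H3K4me1 and H3K4me3 peaks of the JQ1 lists. The lowest ratio was 3.54 kb in DMSO to 1.65 kb in JQ1 on chromosome 1 at 17012006 to 17015546, followed by 3.26 to 2.07 kb on chromosome 18 at 12405869 to 12409220. Among peaks in 1 list only, the widest in JQ1 were 6.51 kb on chromosome 4 at 191027472 to 191033986, which overlapped none of the other 5 JQ1 lists, and 5.65 kb on chromosome 12 at 11880855 to 11886508, which overlapped RNA polymerase II and all 3 marks. The widest in DMSO only was 7.33 kb on chromosome 6 at 74220094 to 74227419, with RNA polymerase II and H3K4me3 in DMSO. With both Myc lists cut to equal length by width, 86.1% of DMSO peaks and 84.1% of JQ1 peaks were shared.

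Myc sites seen in 1 condition only, whether JQ1 or DMSO, lay less often at H3K4me3 than the sites seen in both. They lay more often at H3K4me1 without H3K4me3, and more often at none of the 3 marks. They were also narrower, with a median width of 1068 against 1720 bases in JQ1 and 970 against 1465.5 bases in DMSO. Width was not held equal here, so marks and width are not told apart. Of Myc JQ1 peaks also present in DMSO, 75.3% (74.6 to 76.0) overlapped H3K4me3 in JQ1, whereas 30.4% (29.3 to 31.5) of the JQ1-only peaks did. H3K4me1 without H3K4me3 lay under 12.6% (12.1 to 13.2) of the peaks in both and 30.2% (29.1 to 31.3) of the JQ1-only peaks. Of the JQ1-only peaks, 19.3% (18.4 to 20.2) had H3K4me1 together with H3K27ac, 10.9% had H3K4me1 alone and 6.64% had H3K27ac alone. Another 32.7% (31.6 to 33.8) had none of the 3 marks, compared with 9.42% (8.96 to 9.91) of the peaks in both. The H3K4me1 classes were counted after H3K4me3, so their share can rise because that of H3K4me3 falls. Outside H3K4me3, 2098 JQ1-only peaks had H3K4me1 and 2271 no mark, against 1844 and 1378 of the peaks in both. No preference for H3K4me1 is therefore read from these shares. The 385 DMSO-only peaks differed from the peaks in both in the same direction, by the DMSO histone lists, with 38.2% (33.3 to 43.2) at H3K4me3, 24.2% (19.96 to 28.75) at H3K4me1 without H3K4me3 and 36.6% (31.8 to 41.7) at none, compared with 77.4%, 13.9% and 8.38% of the DMSO peaks in both. The share of all Myc peaks at H3K4me3 was 76.4% (75.7 to 77.1) in DMSO and 60.9% (60.2 to 61.5) in JQ1. In the DMSO histone lists, 36.1% (35.0 to 37.2) of the JQ1-only Myc peaks overlapped H3K4me1 without H3K4me3. Seen from the enhancer mark, 37.0% (36.2 to 37.8) of H3K4me1 peaks overlapped Myc in DMSO and 55.3% (54.3 to 56.3) in JQ1. H3K4me1 peaks moved by 200 kb gave 8.19% and 12.4%, so the background was also higher in JQ1, by about the same factor. The combined class of H3K4me1 and H3K27ac is not comparable between conditions, because with the histone lists exchanged its share of all Myc peaks went from 1.88% to 8.95% in DMSO and from 12.2% to 1.92% in JQ1.

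**Figure D2:**
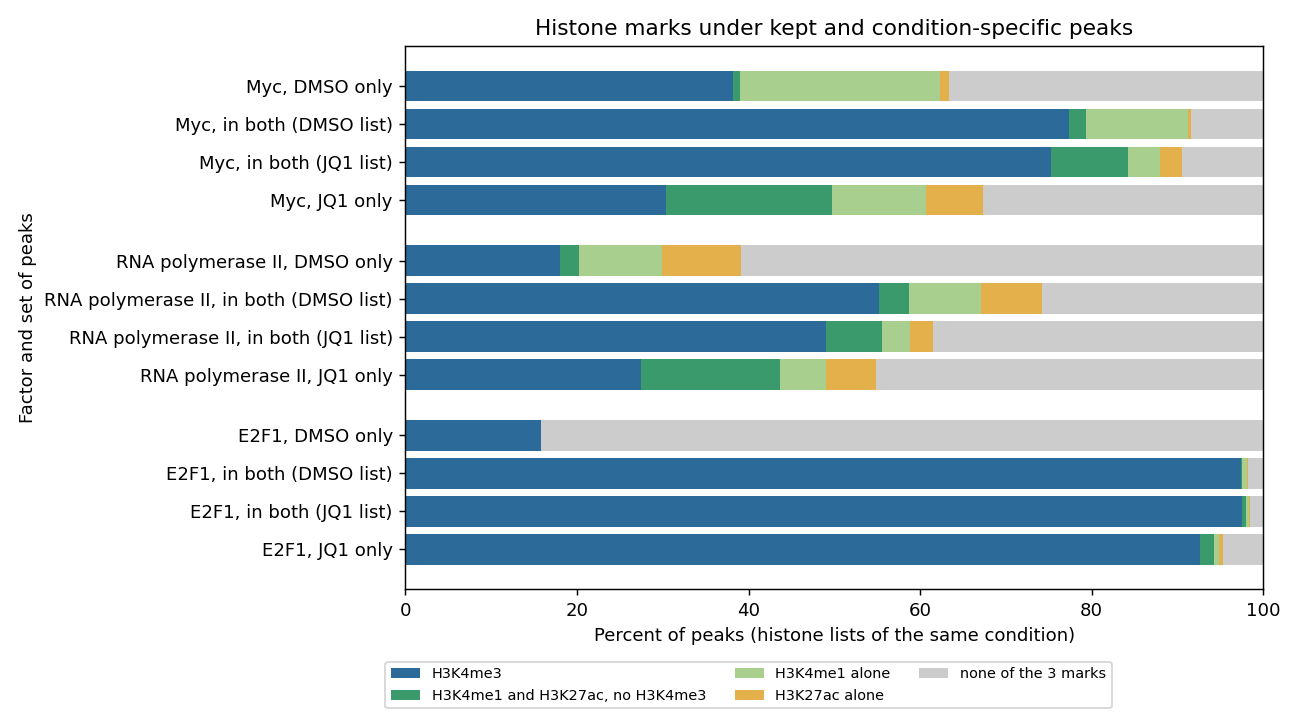
Percent of peaks (horizontal axis) of Myc, RNA polymerase II and E2F1 in each histone class, for peaks in DMSO only, in both conditions (counted in each list) and in JQ1 only (vertical axis), with colours for the classes. JQ1-only Myc peaks overlapped H3K4me3 in 30.4% of cases and Myc peaks in both in 75.3%, and 60.8% of DMSO-only RNA polymerase II peaks overlapped none of the 3 marks. The H3K27ac classes of DMSO rest on the list that lay close to RNA polymerase II.

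RNA polymerase II covered less of the genome in JQ1, and the gap was larger outside H3K4me3 than inside. Inside H3K4me3 peaks of the same condition it covered 20.5 Mb in DMSO and 16.9 Mb in JQ1, which is 17.2% lower. Outside, it covered 25.5 and 15.0 Mb, which is 41.1% lower, so that the part inside went from 44.5% to 53.0% of its bases. Long stretches were fewer. After joining peaks closer than 1 kb, 1075 domains of 10 kb or more were found in DMSO and 548 in JQ1, and 238 and 130 of 20 kb or more. Depth is unknown, so for these covered bases and domains a less sensitive JQ1 library cannot be told apart from an effect of the treatment. Of the DMSO peaks, 54.1% (53.6 to 54.6) overlapped a JQ1 peak, against 5.13% when moved by 200 kb, and 77.8% (77.4 to 78.2) of the JQ1 peaks overlapped a DMSO peak, against 6.34%. That left 21370 peaks in DMSO only and 9408 in JQ1 only. DMSO peaks overlapping H3K4me3 were found again in JQ1 in 78.3% (77.6 to 78.9) of cases. Those up to 5 kb away were found again in 40.5% (39.3 to 41.6) and those 5 to 20 kb away in 40.9% (40.0 to 41.9). Peaks at H3K4me3 were wider, with 23.7 Mb in 17757 peaks against 5.90 Mb in 6989 peaks up to 5 kb away. DMSO-only peaks made up 69.4% of the DMSO peaks under 500 bases and 3.22% of those of 2 kb or more. Width was not held equal, so position or marks and width are not told apart. Of the DMSO-only peaks 60.8% (60.2 to 61.5) overlapped none of the 3 marks, compared with 25.8% (25.3 to 26.4) of the DMSO peaks in both. In the 22844 regions shared by both lists, the median log2 ratio of covered bases was −0.25, with 74.1% of regions wider in DMSO. Peak overlap depended on how peaks were matched: at a reciprocal overlap of 50%, the shares were 33.5% of DMSO peaks and 36.7% of JQ1 peaks.

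**Figure D3:**
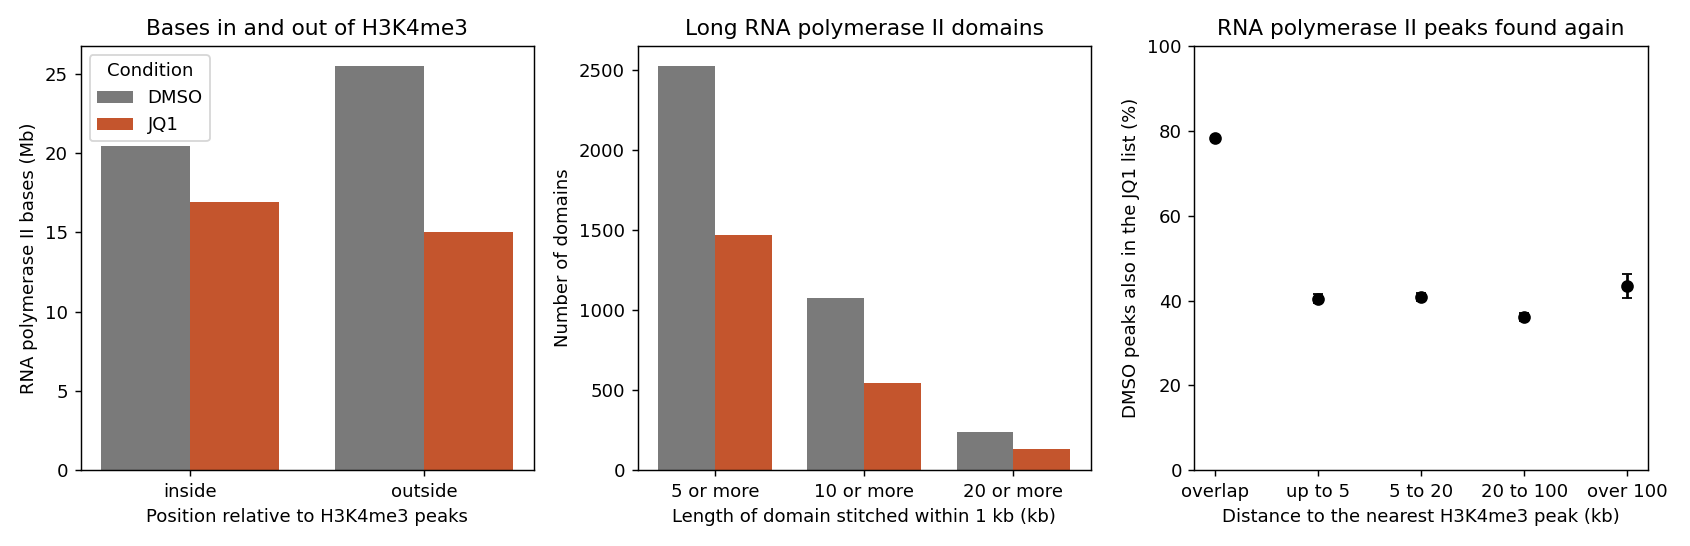
RNA polymerase II bases inside and outside H3K4me3 peaks (left, Mb), number of RNA polymerase II domains by minimum length in kb (middle), and percent of DMSO peaks also found in JQ1 by distance in kb to the nearest H3K4me3 peak of DMSO (right, points with exact 95% intervals). Grey bars are DMSO and orange bars JQ1, 1 library each. Bases outside H3K4me3 were 25.5 Mb in DMSO and 15.0 Mb in JQ1, and domains of 10 kb or more numbered 1075 and 548.

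Named RNA polymerase II shared regions had at least 5 kb covered in both lists together, so those with the lowest ratio are long by that rule. The 5 with the lowest ratio of JQ1 to DMSO had no H3K4me3 or Myc peak in DMSO. The region on chromosome 15 at 44175422 to 44185093 went from 9.67 kb covered in DMSO to 0.217 kb in JQ1, that on chromosome 21 at 46923604 to 46930718 from 7.11 to 0.207 kb, and that on chromosome 9 at 123608964 to 123615827 from 6.80 to 0.246 kb. Regions on chromosome 7 at 73637136 to 73642558 and on chromosome 17 at 79688883 to 79694041 went from 5.42 to 0.197 kb and from 5.16 to 0.264 kb. None of these 5 overlapped a Myc, E2F1 or H3K4me3 peak of the DMSO lists. Among the regions with the highest ratio, RNA polymerase II covered 0.942 kb in DMSO and 5.49 kb in JQ1 on chromosome 18 at 60824585 to 60830071, and 1.06 and 5.36 kb on chromosome 6 at 159461059 to 159466417, and both overlapped Myc and all 3 marks in JQ1. A region on chromosome 20 at 44703436 to 44707947, from 0.952 to 4.51 kb, overlapped none of the other 5 JQ1 lists. The widest DMSO-only peak was 7.47 kb on chromosome 16 at 58531114 to 58538581 and the widest JQ1-only peak 7.82 kb on chromosome 17 at 41409138 to 41416961. The RNA polymerase II peaks in JQ1 only overlapped H3K4me3 in 27.5% (26.6 to 28.4) of cases, compared with 18.1% (17.6 to 18.6) of the DMSO-only peaks. They had H3K4me1 without H3K4me3 in 21.5% (20.7 to 22.4), compared with 11.9% (11.5 to 12.3).

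E2F1 was found almost entirely at H3K4me3 in both conditions. Of its peaks, 91.3% (90.5 to 92.1) in DMSO and 95.1% (94.6 to 95.5) in JQ1 overlapped H3K4me3. The peaks in JQ1 only were also at H3K4me3, in 92.7% (91.8 to 93.4) of cases. H3K4me3 peaks with E2F1 made up 28.0% (27.3 to 28.8) in DMSO and 57.0% (56.1 to 57.8) in JQ1. Moved by 200 kb, H3K4me3 peaks gave 1.60% and 4.12%, a rise by a larger factor. The E2F1 list of JQ1 also covered 6.62 times as many bases as that of DMSO, so no gain of E2F1 is read from these shares. Unlike the JQ1-only peaks, 84.3% (80.1 to 87.9) of the 362 E2F1 peaks in DMSO only overlapped none of the 3 marks. These include the 11 DMSO peaks on mitochondrial DNA, where the histone lists of DMSO hold no peak. E2F1 DMSO peaks overlapped a JQ1 peak in 92.5% (91.7 to 93.2) of cases and JQ1 peaks a DMSO peak in 49.4% (48.3 to 50.5). All 4013 shared regions were wider in JQ1, with a median log2 ratio of covered bases of 1.92. The regions with the highest ratio included chromosome 3 at 75742530 to 75753815, from 0.275 to 11.3 kb, which had H3K4me3 but neither Myc nor RNA polymerase II, and chromosome 5 at 139027016 to 139032610, from 0.186 to 5.59 kb, which had Myc, RNA polymerase II and all 3 marks. The widest DMSO-only peak was 2.90 kb on chromosome 6 at 58776474 to 58779378. The widest JQ1-only peak was 10.1 kb on chromosome 21 at 9422146 to 9432268, and neither overlapped Myc or RNA polymerase II. Regions prone to false peaks were not removed from any list here, so whether the named regions are binding sites was not tested. Because the 2 E2F1 lists differ in width throughout, at a reciprocal overlap of 50% only 2.80% of DMSO peaks and 1.66% of JQ1 peaks were shared.

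Myc, E2F1 and RNA polymerase II occupied common places in both conditions. Of the Myc peaks, 74.5% (73.8 to 75.2) overlapped RNA polymerase II in DMSO and 61.3% (60.7 to 62.0) in JQ1, against 7.57% and 5.49% for Myc peaks moved by 200 kb. E2F1 overlapped 24.8% (24.1 to 25.5) of Myc peaks in DMSO and 35.8% (35.2 to 36.5) in JQ1, against 0.869% and 2.52%. That background rose by a larger factor than the share, and the E2F1 list of JQ1 covered 6.62 times as many bases as that of DMSO. No gain of E2F1 at Myc peaks is therefore read from these shares. Most E2F1 peaks overlapped Myc, at 86.6% (85.6 to 87.6) in DMSO and 93.7% (93.1 to 94.2) in JQ1. By the Jaccard index, the E2F1 JQ1 list had 0.424 with Myc DMSO, 0.351 with Myc JQ1 and 0.144 with E2F1 DMSO. The E2F1 DMSO list covered only 2.70 Mb, which keeps the last value low, and 96.1% of its bases lay in the E2F1 JQ1 list. Whether the E2F1 JQ1 library was mixed or mislabelled was not tested, so its overlap with Myc is given for the list with that label. The direction for RNA polymerase II depended on which peaks were kept. When all lists were cut to 1 length in both conditions, 4820 peaks, keeping the widest, its share of Myc peaks was 45.2% in DMSO and 48.3% in JQ1, the opposite direction, and at 15247 peaks it was 50.2% and 55.9%, a choice made after the data were seen.

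H3K4me3 was the most alike of the 6 antibodies between conditions by the Jaccard index. Of the DMSO peaks, 92.0% (91.6 to 92.5) overlapped a JQ1 peak and 97.9% (97.7 to 98.2) of the JQ1 peaks overlapped a DMSO peak, and the median log2 ratio of covered bases in shared regions was −0.01. That index, the shared bases divided by the bases in either list, was 0.757. The widest H3K4me3 peak in DMSO only was 13.3 kb on chromosome 12 at 65578046 to 65591362, and the widest in JQ1 only 38.8 kb on chromosome 21 at 11109405 to 11148189. The lowest ratio in a shared region was 7.449 kb in DMSO to 1.504 kb in JQ1 on chromosome 2 at 64313123 to 64320628. The H3K4me1 list was shorter in JQ1, with 60.5% (59.7 to 61.3) of the DMSO peaks found in JQ1 and 84.4% (83.6 to 85.1) of the JQ1 peaks found in DMSO. That left 5658 H3K4me1 peaks in DMSO only and 1578 in JQ1 only, while in shared regions the median log2 ratio was 0.02. The widest H3K4me1 peak in DMSO only was 48.3 kb on chromosome 4 at 40202551 to 40250850, and the next 39.5 kb on chromosome 13 at 99188080 to 99227595. The widest in JQ1 only was 25.8 kb on chromosome 6 at 157298446 to 157324210. The lowest H3K4me1 ratio in a shared region was 13.8 kb in DMSO to 1.95 kb in JQ1 on chromosome 4 at 151892210 to 151906056. With both H3K4me1 lists cut to equal length by width, 69.2% of DMSO peaks and 68.5% of JQ1 peaks were shared.

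The H3K27ac lists differed in place as well as in number. Of the peaks in the list labelled H3K27ac DMSO, 85.2% (84.4 to 86.1) overlapped an H3K27ac JQ1 peak, and 48.4% (47.5 to 49.3) of the JQ1 peaks overlapped a DMSO peak, but only 55.1% and 31.3% of bases were shared. With both lists cut to equal length by width the shares of peaks were 46.2% and 44.7%, and at a reciprocal overlap of 50% they were 42.3% and 23.8%. The H3K27ac JQ1 list had a Jaccard index of 0.337 with H3K4me1 JQ1 and 0.320 with H3K4me3 JQ1, both above its 0.249 with the DMSO list. The index alone thus does not say which list is the odd one. For the list labelled H3K27ac DMSO, the index was 0.249 with H3K27ac JQ1, 0.341 with RNA polymerase II DMSO and 0.356 with H3K4me3 DMSO. Of its peaks, 99.1% (98.8 to 99.3) overlapped RNA polymerase II in DMSO, and outside H3K4me3 39.5% of its bases lay under RNA polymerase II and 24.4% under H3K4me1 in DMSO. In the H3K27ac JQ1 list, the bases outside H3K4me3 lay under RNA polymerase II JQ1 peaks in 6.47% and under H3K4me1 JQ1 peaks in 66.6%. The 6114 H3K27ac peaks in JQ1 only overlapped H3K4me1 in 54.9% (53.7 to 56.2), Myc in 66.8% (65.6 to 68.0) and RNA polymerase II in 57.2% (55.9 to 58.4) of cases, all in JQ1. For the 5745 JQ1 peaks in both, these shares were 37.6%, 96.8% and 99.3%. The JQ1-only peaks thus had more H3K4me1 and less of the others. However, the peaks in both were chosen by overlap with the list labelled H3K27ac DMSO. Of the peaks in that list, 99.1% overlapped RNA polymerase II and 88.7% Myc in DMSO. That choice favours both proteins among the peaks in both, so these differences are not read as a trait of the JQ1-only peaks. The widest JQ1-only peaks spanned 83.7 kb on chromosome 13 at 47124793 to 47208479, 56.6 kb on chromosome 8 at 81968829 to 82025423 and 55.8 kb on chromosome 9 at 125976635 to 126032401. The widest in DMSO only was 28.1 kb on chromosome 17 at 38442141 to 38470269. The highest ratio in a shared region was 0.787 kb in DMSO to 20.8 kb in JQ1 on chromosome 2 at 198062634 to 198083450, and the lowest 9.24 to 0.434 kb on chromosome 8 at 145630472 to 145639714. No direction for H3K27ac is drawn from these lists.

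**Figure D4:**
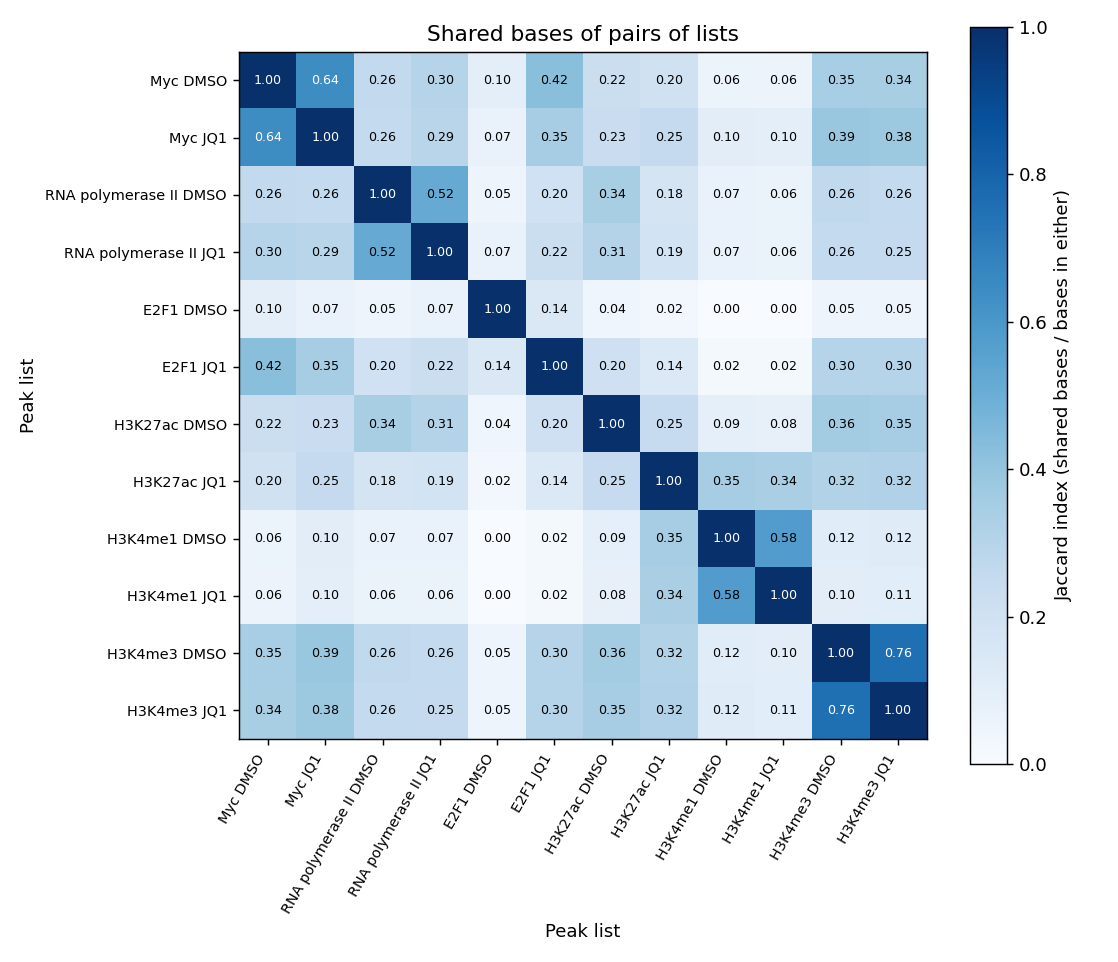
Jaccard index (shared bases divided by bases in either list, colour and number in each cell, from 0 to 1) for all pairs of the 12 peak lists, named on both axes. H3K4me3 reached 0.757 between conditions, and the list labelled H3K27ac DMSO had 0.249 with H3K27ac JQ1 and 0.341 with RNA polymerase II DMSO.

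Long domains were built by joining nearby peaks of the list labelled H3K27ac DMSO, which gave 5900 domains, and taking the longest 5%. These were 295 domains of at least 24860 bases over 10.6 Mb. RNA polymerase II covered 53.2% of their bases in DMSO and 40.0% in JQ1, compared with 45.9% and 36.3% in the other 5605 domains. The list they come from lies close to RNA polymerase II of DMSO, so its domains favour a high RNA polymerase II cover in DMSO. Over the whole lists, RNA polymerase II covered 0.696 times as many bases in JQ1, so a fall is not particular to these domains. Myc covered 18.3% in DMSO and 21.9% in JQ1 of the long domains, compared with 28.4% and 33.8% of the others. H3K27ac JQ1 peaks covered 41.1% of the long domains and 55.8% of the others. When the domains were built from the JQ1 list, a choice made after the data were seen, the 483 longest had RNA polymerase II over 17.9% of their bases in DMSO and 18.9% in JQ1, while the other 9164 had 23.5% and 20.4%. Of these 4 sets of domains, only the long ones from the JQ1 list did not have a lower RNA polymerase II cover in JQ1. The sets from the list labelled H3K27ac DMSO favour a higher cover in DMSO by their choice, so their falls are not read as an effect on acetylated domains.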

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

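All tests of explanations in this part were chosen after the result they concern was seen. The difference between antibodies was not tested, since each condition has 1 library. The lists labelled H3K27ac and H3K4me1, marks both found at active regulatory DNA, differed in opposite ways in length. The JQ1 list held 1.78 times as many peaks as the DMSO list for H3K27ac and 0.704 times as many for H3K4me1. No direction for H3K27ac is read from this, because of the doubt about the list labelled H3K27ac DMSO. On mitochondrial DNA, to which no comparison was devoted, the E2F1 list of DMSO held 11 peaks and that of JQ1 held 0. These 11 are among the E2F1 peaks in DMSO only.

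The list labelled H3K27ac DMSO stands apart from its JQ1 partner and lies close to RNA polymerase II. The H3K27ac JQ1 list was also less like its partner, with a Jaccard index of 0.249, than like H3K4me1 JQ1 (0.337) and H3K4me3 JQ1 (0.320). The index alone therefore does not say which of these H3K27ac lists is the odd one. A lower sensitivity of the DMSO library as the whole cause is argued against by covered bases only. Of the bases of the DMSO list, 44.9% lie outside the longer JQ1 list, more than the 20% set as the bound after the lists were seen. By peaks the measure differs, since 85.2% of the DMSO peaks overlapped a JQ1 peak. For H3K4me1, 84.4% of the peaks of the shorter JQ1 list overlapped a DMSO peak. A mislabelled or mixed library stays possible. Outside H3K4me3, 39.5% of the bases of the DMSO list lie under RNA polymerase II DMSO peaks and 24.4% under H3K4me1. In the JQ1 list H3K4me1 covers far more than RNA polymerase II. These values describe the same closeness to RNA polymerase II that is to be explained, so they do not test this explanation. A movement of acetylation by the treatment cannot be told apart from a mislabelled or mixed library with 1 library per condition, and 22.1% of the DMSO bases outside H3K4me3 were shared with the JQ1 list. A second H3K27ac library of each condition would help to separate the explanations.

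E2F1 peaks were wider in JQ1 in every shared region. Peak calling that differed between the lists may explain the widths, but this could not be tested. Of the DMSO peaks, 45.3% are narrower than the narrowest JQ1 peak, and for the other 5 antibodies the same share was at most 0.299% in either direction. That share comes from the widths to be explained, so it does not tell peak calling from other differences between the libraries. A deeper JQ1 library stays open, because the JQ1-only peaks had a median width 3.66 times that of the DMSO peaks, but any 4109 peaks of that list would have given at least 3.36 times. Whether E2F1 binding also changed with the treatment was not tested, and the 4109 JQ1-only E2F1 peaks rest on this pair of lists. A mixed or mislabelled E2F1 library was not tested either.

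RNA polymerase II covered fewer bases in JQ1. Of the 5126 shared regions with at least 2 kb covered in either list, 1.81% (exact 95% interval 1.47 to 2.22) covered more than 2 times as many bases in JQ1 and 17.1% in DMSO, while H3K4me3, the pair of lists most alike, had 2.53% and 1.18%. Over all 22844 shared regions, however, the share with more in JQ1 was 2.78% (2.566 to 2.997), above the 2.35% and 1.14% of H3K4me3, and 22.2% of the RNA polymerase II JQ1 peaks were found in JQ1 only, against 2.06% of the JQ1 and 7.98% of the DMSO peaks of H3K4me3 found in 1 condition only. The JQ1-only peaks made up 33.6% of the JQ1 peaks under 500 bases, where H3K4me3 had too few peaks, 34 in DMSO and 5 in JQ1, to compare. At 500 to 1000 bases they made up 11.5%, between the 7.64% of JQ1 and 39.9% of DMSO peaks of H3K4me3. At 1 to 2 kb the values were 2.89%, 5.58% and 17.9%, and at 2 kb or more 0.655%, 1.09% and 2.88%, so RNA polymerase II was below both. In shared regions of 1 to 2 kb, however, the share with more than 2 times as many bases in JQ1 was 3.58%, above the 1.63% in JQ1 and 1.13% in DMSO of H3K4me3. Lower sensitivity of the JQ1 library as the whole cause cannot be told apart from an effect of the treatment, because these values point both ways and each condition has 1 library of unknown depth.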

How the results depend on the processing

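Windows of 200 bases, merging within 500 bases, domains from the JQ1 list, lists of 1 length in both conditions, the exchanged H3K4me3 list for covered bases and the joining distances of RNA polymerase II were chosen after seeing the data. Of 89 alternative values for 44 results, 65 moved, taken as beyond the 95% interval, or, for covered bases, by 1% or more of their size. The other 24 did not. Ratios of peak numbers stayed within 1.5 times of the main ones and on their side of 1, on autosomes and X for all 6 antibodies and after merging for Myc, RNA polymerase II and E2F1, which alone were merged. The ratio of RNA polymerase II domains of 10 kb or more, 0.510, was 0.468 and 0.573 when joined within 0.5 and 2 kb. No paired analysis was possible because each condition has 1 library. Thresholds on p and a false discovery rate, tag scalings and promoter windows were not run, as the lists hold no such values and no hg19 annotation was used. Depth is unknown, so what it limits could not be measured. The cause of each move was not tested.

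At a reciprocal overlap of 50%, the shares of DMSO peaks found in JQ1 and of JQ1 peaks found in DMSO were 92.4% and 65.4% for Myc, 33.5% and 36.7% for RNA polymerase II, 2.80% and 1.66% for E2F1, 42.3% and 23.8% for H3K27ac, 52.1% and 74.0% for H3K4me1, and 86.7% and 92.3% for H3K4me3. With lists of equal length, planned by p and done by width, they were 86.1% and 84.1%, 57.2% and 76.2%, 68.3% and 60.2%, 46.2% and 44.7%, 69.2% and 68.5%, and 94.3% and 94.3%, in the same order. With the central 200 bases they were 78.9% and 55.8% for Myc, 36.7% and 40.6% for RNA polymerase II, and 50.4% and 29.7% for E2F1. After merging, 68.8% of Myc JQ1, 61.5% of RNA polymerase II DMSO and 93.5% of E2F1 DMSO peaks were shared. Broad peaks of 1 kb or more gave 93.0% and 96.6% for H3K4me3.

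With exchanged histone lists, H3K4me3 lay under 74.4% of Myc DMSO, 62.7% of Myc JQ1, 32.0% of JQ1-only Myc, 36.9% of RNA polymerase II DMSO, 17.0% of its DMSO-only, 45.4% of RNA polymerase II JQ1 and 20.7% of DMSO-only E2F1 peaks. H3K4me1 with H3K27ac lay under 8.95% of Myc DMSO, 1.92% of Myc JQ1, 6.17% of RNA polymerase II DMSO and 3.37% of RNA polymerase II JQ1 peaks, so that the order of the conditions turned round. RNA polymerase II bases inside H3K4me3 were 43.4% in DMSO and 54.0% in JQ1. In lists cut to the shortest of each condition, which is E2F1 with 4820 peaks in DMSO and 8122 in JQ1, Myc peaks overlapped E2F1 in 45.8% and 64.4% and RNA polymerase II in 45.2% and 53.9%, in DMSO and JQ1. At 4820 peaks in both conditions these were 45.8% and 55.4% for E2F1 and 45.2% and 48.3% for RNA polymerase II. At 15247 peaks RNA polymerase II had 50.2% and 55.9%. The order for RNA polymerase II turned round in each, and each also keeps only the widest peaks, so length and width are not separated. In long domains, RNA polymerase II DMSO, RNA polymerase II JQ1 and H3K27ac JQ1 covered 66.5%, 50.01% and 42.4% when joined within 5 kb and 53.5%, 40.4% and 42.4% for the longest 10%. In domains from the JQ1 list RNA polymerase II covered 17.9% and 18.9%.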

Other observations

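The H3K4me1 list shortened unevenly over chromosomes. On chromosome X, 133 H3K4me1 peaks were listed in DMSO and 54 in JQ1, so that its share of the list was 0.927% (exact 95% interval 0.777 to 1.10) and 0.535% (0.402 to 0.697). The list labelled H3K27ac DMSO, which is in doubt as an H3K27ac library, held 215 peaks on chromosome 8 and the H3K27ac JQ1 list 508, or 3.23% (2.82 to 3.68) and 4.28% (3.93 to 4.66) of each list. On chromosome 19 they held 439 and 579, or 6.59% (6.00 to 7.21) and 4.88% (4.50 to 5.29). These chromosomes were picked after the values of all chromosomes were seen.

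The H3K4me3 peaks found in 1 condition only were few, and they overlapped H3K4me1 more often and Myc less often than the H3K4me3 peaks in both. They were also narrower, with a median width of 1266 against 3394.5 bases in DMSO and 1679.5 against 3420 bases in JQ1. Width was not held equal in these shares. Of the 12828 DMSO peaks in both, 39.0% (38.2 to 39.9) overlapped H3K4me1 of DMSO, 76.5% (75.7 to 77.2) Myc of DMSO and 84.8% (84.2 to 85.4) Myc of JQ1. Of the 270 found in JQ1 only, 73.3% (67.6 to 78.5) overlapped H3K4me1 peaks of DMSO, 58.5% (52.4 to 64.5) overlapped Myc peaks of JQ1 and 31.9% (26.3 to 37.8) Myc peaks of DMSO. Of the 1113 found in DMSO only, 49.9% (46.9 to 52.8) overlapped H3K4me1 of DMSO, 30.8% (28.1 to 33.6) Myc of DMSO and 46.4% (43.4 to 49.3) Myc of JQ1. For H3K4me3 peaks moved by 200 kb, the overlap with Myc of DMSO and of JQ1 was 6.25% and 8.24% for those in both, 2.04% and 4.07% for those in JQ1 only and 3.14% and 4.58% for those in DMSO only. The background was thus also higher in JQ1, and lower for the peaks in 1 condition only, so neither a gain of Myc nor its depletion relative to background is read from these shares.

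The one test here that was planned before its result was seen concerns a hypothesis. It was that Myc and RNA polymerase II appear at common places after JQ1. Of the 6941 Myc peaks in JQ1 only, 11.9% (11.2 to 12.7) overlapped an RNA polymerase II peak in JQ1 only and 5.17% (4.66 to 5.72) an RNA polymerase II peak in DMSO only, although the second list is longer, with 21370 against 9408 peaks. Moved by 200 kb, the shares were 0.828% and 2.31%. The overlap was therefore 14.4 and 2.24 times that of the moved peaks. Myc peaks found in both conditions had 8.43% (7.99 to 8.90) and 10.97% (10.5 to 11.5), against 1.25% and 3.29% when moved, or 6.76 and 3.34 times. The higher ratio for RNA polymerase II peaks in JQ1 only was thus not limited to the JQ1-only Myc peaks. The values are consistent with a gain of both at part of these places, but do not show that it is particular to them. Most of the JQ1-only Myc peaks had no RNA polymerase II peak, since 30.9% (29.8 to 32.0) overlapped any RNA polymerase II peak of JQ1. Already 24.6% (23.6 to 25.6) of these Myc peaks overlapped an RNA polymerase II peak of DMSO. That limits the part that a gain of both could cover. A background common to the JQ1 libraries was not tested and may give the same overlap.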
